A study of Mus musculus with 6 samples.

How the data were processed

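RNA-seq was compared in 6 libraries of neutrophils sorted from the uteri of PRPL mice, 3 from mice in ambient air and 3 from mice in 60% oxygen. RNA was isolated with a column kit for small samples and made into libraries with an Ovation/NexteraXT kit, per the labels' protocols. The authors deposited 1 table of raw counts per gene for each library, with whole numbers and no normalization. Reads were aligned with STAR 2.4.2a to the mouse genome build GRCm38, and DESeq2 1.16.1 is also named, per the submitters' processing notes. The counting program, its strand setting and the annotation release were not given in the sources used here. Without a strand setting, reads of genes that overlap on opposite strands cannot be told apart, and reads shared by near-identical copies may have been dropped or misplaced.

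Each table listed 43432 Ensembl gene IDs. Of these, 42548 matched GENCODE M21 by ID and took their symbols and GRCm38 coordinates from it; the 884 others held at most 0.25% of a library's counts and kept their IDs. Libraries held 38683293 to 61715617 counts, 98.7% to 98.9% of them on protein-coding genes, 0.26% to 0.38% on mitochondrial genes and 0.08% to 0.13% on ribosomal protein genes. The 10 most abundant genes took 19.8% to 22.2% of a library. A floor of 3 counts corresponded to between 0.0486 and 0.0776 CPM, which are counts scaled by library size. Intervals of counts cover counting error only, since reads copied by PCR are not independent molecules. No pair of libraries matched within sampling noise, with chi-square values per degree of freedom of 32.2 to 851, so all 6 were kept as separate samples.

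Groups were taken from the housing condition in the labels. The labels do not state that the libraries came from separate animals, litters or batches, so p-values measure the spread between these samples, which may be technical in part. Replicate numbers follow the order of deposition and pair nothing. Counts were analysed with edgeR 4.0.16 in R 4.3.3: genes were filtered with filterByExpr at default settings, which left 12908 of 23147 genes with a count, library sizes were scaled by TMM, and a robust quasi-likelihood test compared the groups, two-sided, with Benjamini-Hochberg adjustment over all genes tested. Standard errors of log2 differences were derived from the F statistic. The biological coefficient of variation was 36.3% and the median standard error of a log2 difference 0.34.

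Before the data were examined, 37 gene lists were fixed, 24 for pathways and 13 for cell types, together with the test, the alternatives and the rule for naming genes. Lists with at least 5 measured members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a correlation between genes preset at 0.01, and again with an estimated correlation and with fry. A list's score was its mean log2 CPM in a library, compared between groups with limma's moderated test and its 95% interval. The named genes were the 10 in each direction with the largest change among genes past the threshold, with groups that do not overlap, an average log2 CPM of at least 3 and a symbol that is not a model name, filled up with the lowest p values where fewer passed; the 3 members of each list with the lowest p; and 15 genes fixed by name. Further list members named for their level or because they passed within the list (Apoe, C1qb, Csf1r, Itgax, Egr2, Ngp) were chosen after their values were seen. A few genes that met these rules are left unnamed for reasons unrelated to their values.

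Alternatives were DESeq2 1.42.0, limma-voom with and without sample quality weights, other scaling factors, no filter or a filter at a mean count of 10 in at least 3 libraries, removal of mitochondrial, ribosomal protein and haemoglobin genes, a threshold of 0.1, a minimum fold of 1.5, and leaving out each library. The procedure was tested on simulated data, with counts drawn from the real means, library sizes and edgeR's dispersions and 200 of 12908 genes changed in each of 5 runs. edgeR recovered 8.36% of genes changed 2-fold, 62.7% of those changed 4-fold and 83.6% of those changed 8-fold, and 50 of its 564 calls were false. DESeq2 recovered 23.0%, 76.7% and 88.2%, and 228 of its 853 calls were false, in a simulation whose dispersions came from edgeR. A 1.5-fold shift of the hypoxia list was called by camera in 5 of 5 runs with the preset correlation and in 2 of 5 with an estimated one, in simulated genes that vary independently.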

Results

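Neutrophils were taken from the uteri of PRPL mice, a cre-lox model of uterine tumours. All mice were of the C57BL/6 strain and 4 weeks old. Either ambient air (the normoxia group) or an environmental chamber at 60% oxygen (the hyperoxia group) surrounded the mice for 10 days, from postnatal day 18 to postnatal day 28. Cells positive for CD45 and CD11b and high for the neutrophil surface protein Ly6G were sorted from digested uteri, and RNA-seq gave 3 libraries per group. The normoxia libraries held 44870447, 42479505 and 38683293 gene counts, and the hyperoxia libraries 44152840, 61715617 and 44803171. Between 17437 and 18984 genes had a count in a library, and 12908 genes were tested. The comparison asked what extra oxygen for the host altered in the RNA of neutrophils from the tumour-bearing uterus.

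Msr1 and Irf8, genes known from macrophages and monocytes, had low p values, with every hyperoxia library above every normoxia library. Msr1, a scavenger receptor of macrophages, averaged 24.8 ± 7.33 CPM in hyperoxia and 5.57 ± 0.487 CPM in normoxia (SD, n = 3 each), a log2 difference of 2.15 ± 0.26 (SE). Irf8, a transcription factor of monocyte and dendritic cell development, averaged 32.3 ± 9.04 against 7.96 ± 0.799 CPM (SD, n = 3 each), a log2 difference of 2.02 ± 0.26 (SE). In the other direction, Gpr146, an orphan G protein-coupled receptor, stood at 94.6, 94.1 and 78.3 CPM in the normoxia libraries and at 37.1, 38.0 and 36.5 CPM in the hyperoxia libraries, a log2 difference of -1.26 ± 0.19 (SE). Their adjusted p of 0.0974 in edgeR's quasi-likelihood test missed the 0.05 threshold, whereas DESeq2 called all of them, with adjusted p of 2.28e-09 for Msr1, 1.43e-08 for Irf8 and 5.51e-06 for Gpr146. Of the 50 genes with the lowest p in edgeR, a number chosen after the data were seen, 48 were higher in hyperoxia and 4 belonged to marker lists of cell types other than neutrophils.

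No gene passed an adjusted p of 0.05 in that test: 0 genes were called higher and 0 lower. At an unadjusted p under 0.05, edgeR counted 1175 genes higher and 505 lower in hyperoxia, where chance alone would give 645 in all. DESeq2 called 461 genes higher and 52 lower on the same counts, limma-voom called 0, and limma-voom with sample quality weights called 36. The libraries of the groups did not overlap for 19.9% of genes, where chance gives 10%; 1235 of these genes were higher in hyperoxia and 1333 lower. Without hyperoxia replicate 1, edgeR called 164 genes higher and 12 lower, of which 150 were also among the DESeq2 calls on all 6 libraries.

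Among genes higher in hyperoxia with an average log2 CPM of at least 3 and groups that do not overlap, the 10 with the lowest p spanned log2 differences of 1.46 to 2.20, each with an adjusted p of 0.0974 in edgeR and each called by DESeq2. Msr1 lies on chromosome 8, 39581685 to 39642673 in GRCm38 (ENSMUSG00000025044), and Irf8 on the same chromosome, 120736358 to 120756694 (ENSMUSG00000041515). C3ar1, the receptor for the complement fragment C3a, differed by 1.91 ± 0.25 (SE), and Tmem119, a membrane protein used as a marker of microglia, by 1.91 ± 0.26. Ms4a7, a membrane protein of macrophages whose relatives have similar sequence, averaged 42.5 ± 17.2 against 10.6 ± 0.501 CPM (SD, n = 3 each) and differed by 2.01 ± 0.31. Ly86, which encodes the partner of an innate receptor, differed by 2.06 ± 0.32, Lpxn, a focal adhesion adaptor, by 2.20 ± 0.33, Phf11d by 2.05 ± 0.29, and Ss18l2 by 1.46 ± 0.23.

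The 10 genes chosen by the same limits in the other direction, all called by DESeq2, had log2 differences between -0.80 and -1.42. After Gpr146 (ENSMUSG00000044197, chromosome 5, 139377697 to 139396415) came Socs1, an inhibitor of cytokine signalling, which averaged 33.5 ± 5.36 CPM in hyperoxia and 77.7 ± 14.5 CPM in normoxia (SD, n = 3 each), a log2 difference of -1.21 ± 0.22 (SE) with an adjusted p of 0.106. Ptger2, a receptor for prostaglandin E, differed by -0.95 ± 0.18 with an adjusted p of 0.106, and Camkk1, a calmodulin-dependent kinase kinase, by -1.42 ± 0.29 with an adjusted p of 0.126. The histone gene Hist1h4i, one of a family of near-identical copies, differed by -1.12 ± 0.21, and the processed pseudogene Gad1-ps by -0.92 ± 0.19; reads of either are uncertain where copies share sequence. Kctd11, Midn, Zkscan14 and Arrdc2 completed the 10, with log2 differences of -0.80, -0.89, -0.82 and -0.87.

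**Figure D1:**
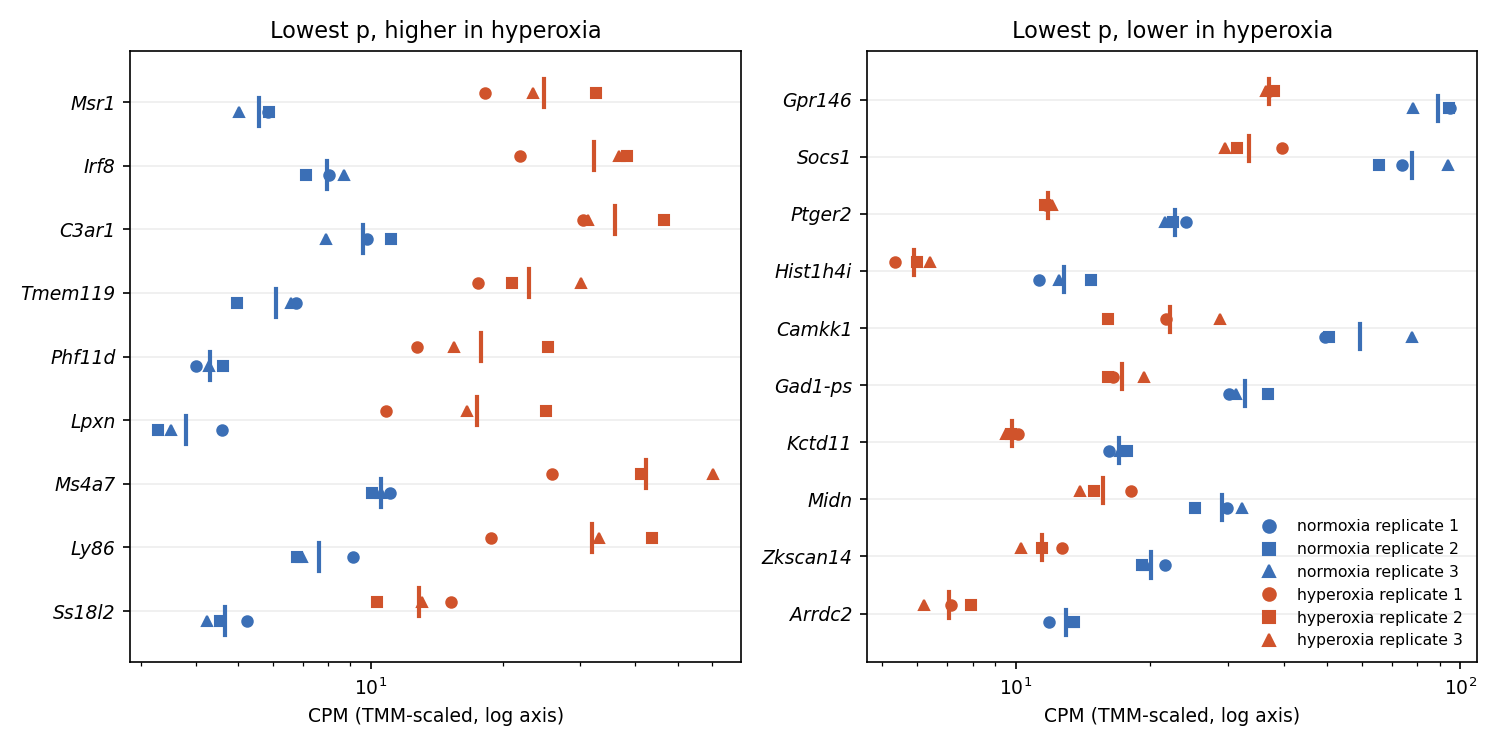
CPM (TMM-scaled, log axis) of the genes with the lowest p in each direction at an average log2 CPM of at least 3, with 1 point per library, normoxia in blue, hyperoxia in orange and a vertical bar at each group mean. Only genes with groups that do not overlap were eligible. Msr1 averages 5.57 CPM in normoxia and 24.8 CPM in hyperoxia.

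Cell types and pathways were compared through gene lists fixed in advance. Of 33 lists with enough measured members, 12 passed an adjusted p of 0.05 in limma's camera test with its preset correlation between genes, 11 higher and 1 lower in hyperoxia. With an estimated correlation 0 of the 33 passed in camera, the lowest adjusted p being 0.431. The fry test, which asks whether a list moves on balance in 1 direction, passed 4. These were the macrophage, protease, lipid metabolism and angiogenesis lists, each with an adjusted p of 0.0408. All other lists past the threshold in camera missed it in fry, where endothelial markers had the lowest adjusted p among them, 0.0799. Marker lists made up 7 of the 12 lists: monocyte and macrophage, MHC class II and dendritic cell, endothelial, stromal, smooth muscle, T and NK cell, and B cell markers. In edgeR, 0 members of any list passed when adjusted over all genes tested. The counts at an unadjusted p under 0.05 and in DESeq2 stand beside each of these 12 lists.

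Monocyte and macrophage markers had a median log2 difference of 1.58 over 14 measured members, 13 of them above 0, with a camera adjusted p of 9.24e-09 and an adjusted p = 0.431 with an estimated correlation. Adjusted over the list alone, 10 of the 14 members passed in edgeR, where 10 were under an unadjusted p of 0.05; DESeq2 called 9 over all genes. Cx3cr1, the fractalkine receptor, averaged 12.8 ± 4.39 against 3.02 ± 0.827 CPM (SD, n = 3 each), and Apoe, a lipid carrier made by macrophages, 1350 ± 449 against 553.7 ± 32.8 CPM (SD, n = 3 each). The complement gene C1qb averaged 170.3 ± 103 against 59.3 ± 5.06 CPM (SD, n = 3 each). Csf1r, the receptor for macrophage colony-stimulating factor, averaged 181 CPM in both groups, with a log2 difference of -0.01 ± 0.22 (SE). The mean log2 CPM of the list lay 1.38 above normoxia (95% interval 0.72 to 2.04, adjusted p of 0.088 in limma).

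Antigen presentation through MHC class II followed the same direction: the MHC class II and dendritic cell list had a median of 1.45 over 10 members, with an adjusted p of 1.07e-04 and an adjusted p = 0.594 with an estimated correlation. Here 7 of the 10 members passed when adjusted over the list alone, 7 were under an unadjusted p of 0.05 and DESeq2 called 6. Cd74, the invariant chain, averaged 721 ± 350.3 CPM against 264 ± 8.33 CPM (SD, n = 3 each) and lay above normoxia in 3 of 3 hyperoxia libraries. H2-Aa had a log2 difference of 1.61 ± 0.40 (SE) and Ciita, the transactivator of these genes, 2.16 ± 0.51, although reads of Ciita may be mixed with those of Dexi on the opposite strand. Itgax, a dendritic cell integrin, had a difference of -0.41 ± 0.32. Without hyperoxia replicate 3 the list's median was 0.94 with an adjusted p of 0.00268.

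Markers of the vessel wall and stroma had higher means in hyperoxia. Endothelial markers had a median log2 difference of 3.34 over 9 members, all above 0, with an adjusted p of 4.24e-08 and an adjusted p = 0.594 with an estimated correlation; 7 passed when adjusted over the list alone, 7 were under an unadjusted p of 0.05 and DESeq2 called 7. Plvap, an endothelial diaphragm protein, averaged 15.3 ± 11.2 against 1.25 ± 0.846 CPM (SD, n = 3 each), and the tight junction gene Cldn5 had a log2 difference of 3.45 ± 0.83 (SE). Tek, the angiopoietin receptor, had 2 counts over the 3 normoxia libraries and 91 over the 3 hyperoxia libraries, a ratio of 38.1 after scaling by library size (95% exact Clopper-Pearson interval 10.2 to 319, covering counting error only). Stromal and fibroblast markers had a median of 2.34 over 11 members, all above 0, with an adjusted p of 8.70e-05 and an adjusted p = 0.594 with an estimated correlation; 9 passed when adjusted over the list alone, 9 were under an unadjusted p of 0.05 and DESeq2 called 6. Among them the growth factor gene Igf1 differed by 2.85 ± 0.70, Postn by 2.34 ± 0.59 and Col3a1, a fibrillar collagen, by 2.53 ± 0.71, but the interval of the list's mean difference ran from -0.16 to 3.91. Relative to the normoxia mean, hyperoxia replicate 1 scored 0.15, below normoxia replicate 3 at 0.84. Only 2 of the 11 stromal members had groups that do not overlap, and without hyperoxia replicate 2 DESeq2 called 1. Smooth muscle markers had a median of 1.17 over 7 members, with an adjusted p of 0.00118 and an adjusted p = 0.594 with an estimated correlation; 5 passed when adjusted over the list alone, 5 were under an unadjusted p of 0.05 and DESeq2 called 3. Actg2 differed by 2.59 ± 0.67, Cnn1 by 2.41 ± 0.69 and Des by 2.47 ± 0.76, and without hyperoxia replicate 2 the smooth muscle median was 0.74 with an adjusted p of 0.015.

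T and NK cell markers had a median log2 difference of 1.05 over 11 members, with an adjusted p of 0.00249 and an adjusted p = 0.594 with an estimated correlation, and B cell markers 1.47 over 6 members, with 0.0241 and 0.594. Adjusted over the list alone, 0 members of either passed in edgeR, while 4 of each were under an unadjusted p of 0.05 and DESeq2 called 1 T cell and 0 B cell markers. Cd3g, a chain of the T cell receptor complex, averaged 2.13 ± 1.41 against 0.424 ± 0.301 CPM (SD, n = 3 each), Cd3e differed by 2.19 ± 0.74 (SE) and Cd3d by 1.05 ± 0.39. Of the B cell receptor genes, Cd79a differed by 1.54 ± 0.55, Cd79b by 1.39 ± 0.53 and the surface protein gene Ms4a1 by 1.64 ± 0.59. Single libraries decided these calls: the T and NK cell list missed the threshold without normoxia replicate 1 (adjusted p of 0.072) or hyperoxia replicate 3 (median 0.38, adjusted p of 0.101), and the B cell list without normoxia replicate 1 (0.082), hyperoxia replicate 2 (median 0.74, 0.186) or hyperoxia replicate 3 (0.101).

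**Figure D2:**
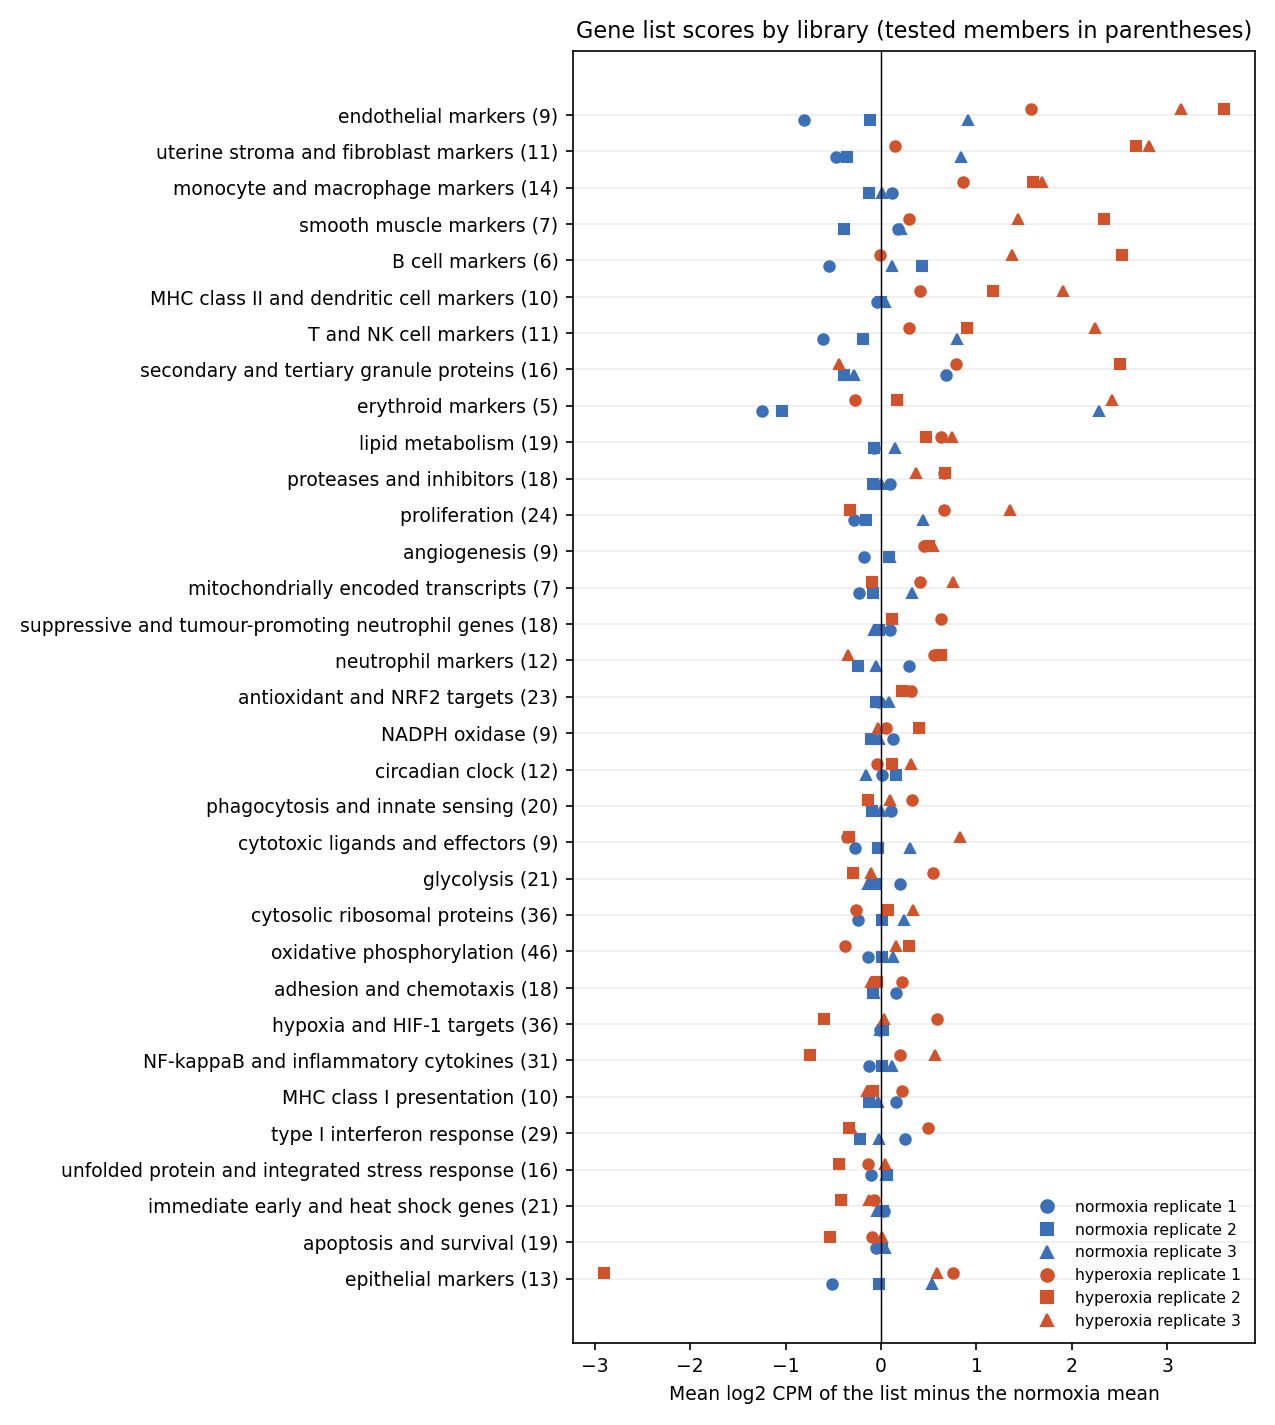
Mean log2 CPM of each tested gene list minus the normoxia mean, with 1 point per library, normoxia in blue, hyperoxia in orange and the number of tested members in parentheses. By the difference of group means, endothelial, stromal, macrophage and smooth muscle markers are the highest 4; hyperoxia replicate 2 lies at -2.90 for epithelial markers and at 2.50 for secondary and tertiary granule proteins.

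Among the pathway lists, 5 passed. Proteases and their inhibitors had a median log2 difference of 0.49 over 18 members, 15 of them above 0, with an adjusted p of 0.00459 and an adjusted p = 0.431 with an estimated correlation; fry gave 0.0408, and the list's mean lay 0.56 above normoxia (95% interval 0.16 to 0.97, adjusted p of 0.137 in limma). Adjusted over the list alone, 3 members passed, 5 were under an unadjusted p of 0.05 and DESeq2 called 3. Mmp14, a membrane-bound matrix metalloproteinase, averaged 22.9 ± 3.93 CPM against 10.0 ± 0.383 CPM (SD, n = 3 each), a log2 difference of 1.19 ± 0.20 (SE). Serpinb2, an inhibitor of plasminogen activators, differed by 2.31 ± 0.53, and Mmp19 by 1.60 ± 0.41, with a strand overlap with Tmem198b. Mean scores of macrophage, endothelial and stromal markers were also higher in hyperoxia, by 1.38, 2.77 and 1.88, although stromal scores overlapped between groups. Without hyperoxia replicate 1 the list had an adjusted p of 0.113, although its median was 0.55.

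Lipid metabolism genes had a median of 0.36 over 19 members, 16 of them above 0, with an adjusted p of 0.0179 and an adjusted p = 0.431 with an estimated correlation; fry gave 0.0408, and the list's mean lay 0.62 above normoxia (95% interval 0.21 to 1.02, adjusted p of 0.123 in limma). Adjusted over the list alone, 4 members passed, 6 were under an unadjusted p of 0.05 and DESeq2 called 4. Among these were the fatty acid binding protein gene Fabp4 (log2 difference 2.85 ± 0.58, SE), the nuclear receptor gene Pparg (1.90 ± 0.41) and the fatty acid transporter gene Cd36 (2.31 ± 0.55), each averaging under 2 CPM in normoxia. Fabp4 and Cd36 are also abundant in endothelium and macrophages, whose markers moved the same way. The list had an adjusted p of 0.0528 without normoxia replicate 2, a median of 0.25 with an adjusted p of 0.169 without hyperoxia replicate 1, and a median of 0.71 without normoxia replicate 3.

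Secondary and tertiary granule proteins, a list of stored proteins and of membrane receptors such as Fpr1, had a median of 1.20 over 16 members, all above 0. Camera gave an adjusted p of 0.00576 and an adjusted p = 0.796 with an estimated correlation. In edgeR 0 members passed when adjusted over the list alone, 6 were under an unadjusted p of 0.05, and DESeq2 called 1, the granule glycoprotein gene Olfm4. Olfm4 averaged 23.8 ± 6.21 against 12.35 ± 2.17 CPM (SD, n = 3 each), and Fpr1, a receptor for formyl peptides that has close relatives, 1831 ± 652 against 932 ± 150.3 CPM (SD, n = 3 each). The chitinase-like gene Chil3 stood at 29.9, 700.3 and 16.2 CPM in the 3 hyperoxia libraries, and without hyperoxia replicate 2 the list's median was 0.36 with an adjusted p of 0.407. The call was also absent without normoxia replicate 2 (0.0528), normoxia replicate 3 (0.0792) or hyperoxia replicate 1 (0.108). Of the primary granule proteins, Mpo, Elane, Ctsg and Bpi were filtered out, with at most 14, 21, 2 and 8 counts in a library. The 4 members measured were too few for camera and had a median of 1.48, or 0.48 without hyperoxia replicate 2. Of these Ctsc, the protease that activates granule serine proteases, passed when adjusted over the list alone (log2 difference 1.63 ± 0.39, SE), whereas Serpinb1a (2.25 ± 0.99, and -0.09 without hyperoxia replicate 2) and Cst7 (1.33 ± 0.68) did not.

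Proliferation genes had a median of 0.75 over 24 members, 21 of them above 0, with an adjusted p of 0.0117 and an adjusted p = 0.854 with an estimated correlation. Adjusted over the list alone, 0 members passed in edgeR, 4 were under an unadjusted p of 0.05 and DESeq2 called 1, the replication helicase gene Mcm5 (log2 difference 1.56 ± 0.44, SE). Rrm2, a ribonucleotide reductase subunit, differed by 1.10 ± 0.41, and the cyclin gene Ccnb2 by 0.90 ± 0.38. Hyperoxia replicate 3 scored 1.35 above the normoxia mean and hyperoxia replicate 2 scored -0.33; without replicate 3 the median was 0.16 with an adjusted p of 0.494. Replicate 3 also had the highest scores for stromal (2.81), T and NK cell (2.24), MHC class II (1.91) and macrophage markers (1.69). The call was likewise absent without normoxia replicate 1 (0.127), normoxia replicate 2 (0.0528) or hyperoxia replicate 1 (0.158).

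Immediate early and heat shock genes formed the list that was lower in hyperoxia, with a median of -0.41 over 21 members, 15 of them below 0, an adjusted p of 0.0343 and an adjusted p = 0.594 with an estimated correlation. Its members went both ways. Adjusted over the list alone, the transcription factor genes Egr2 and Atf3 passed as lower (log2 differences of -0.68 ± 0.21 and -0.76 ± 0.23, SE), and Klf4 (1.45 ± 0.28), Hspa1a (1.09 ± 0.32) and Hspa1b (1.13 ± 0.34) passed as higher. The heat shock genes Hspa1a and Hspa1b are near-identical copies, so their separate values are uncertain. At an unadjusted p under 0.05, 7 members were lower and 4 higher, and DESeq2 called 0 lower and 3 higher. The list missed the threshold without normoxia replicate 1 (0.0957), hyperoxia replicate 2 (median -0.23, 0.0871) or hyperoxia replicate 3 (0.0885).

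Oxygen-responsive genes did not differ as a list. The 36 hypoxia and HIF-1 targets had a median of 0.13, while camera put them on the lower side (adjusted p of 0.929) and the mean differed by 0.01 (95% interval -0.78 to 0.79, limma), so median and test differed in sign. In edgeR 0 members passed when adjusted over the list alone, 0 were under an unadjusted p of 0.05, and DESeq2 called 0. The prolyl hydroxylase gene P4ha2 differed by 1.17 ± 0.56 (SE), Ankrd37 by -0.75 ± 0.37, with a strand overlap with Ufsp2, and the enolase gene Eno1 by 0.54 ± 0.29. The hyperoxia libraries scored 0.58, -0.59 and 0.03 relative to the normoxia mean. Leaving out a single library changed the result in opposite ways: without hyperoxia replicate 1 the median was -0.20 with an adjusted p of 0.00187, and without hyperoxia replicate 2 it was 0.34 with an adjusted p of 0.0154. Hif1a, which encodes the oxygen-regulated transcription factor subunit, differed by -0.20 ± 0.37, the glucose transporter gene Slc2a1 by -0.06 ± 0.37 and Vegfa, the endothelial growth factor, by 0.25 ± 0.24. Without hyperoxia replicate 1, Hif1a stood at -0.73, Slc2a1 at -0.53 and Vegfa at 0.05, and without hyperoxia replicate 2 at 0.10, 0.26 and 0.42. Hif1a and Slc2a1 also turned sign without normoxia replicate 1, and Slc2a1 without hyperoxia replicate 3. Glycolysis genes had a median of 0.07 over 21 members with an adjusted p of 0.929. Among them Gpi1 differed by 0.52 ± 0.30 and Hk3 by 0.47 ± 0.29, and the list's median was -0.20 with an adjusted p of 0.0318 without hyperoxia replicate 1, 0.28 with 0.186 without hyperoxia replicate 2 and 0.20 with 0.591 without normoxia replicate 1.

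The NADPH oxidase, which makes the neutrophil's superoxide, had a list median of -0.01 over 9 members with an adjusted p of 0.929. The sign of so small a median turned with DESeq2 size factors, with upper-quartile scaling and without normoxia replicates 1 or 3 or hyperoxia replicates 1 or 3, the highest value being 0.13 without normoxia replicate 1. Cybb, which encodes its catalytic subunit (ENSMUSG00000015340, chromosome X, 9435252 to 9487771), stood at 69.2, 223.9 and 46.0 CPM in hyperoxia and 45.6, 20.5 and 22.5 CPM in normoxia. Its log2 difference was 1.94 ± 0.59 (SE) with an adjusted p of 0.243 in edgeR and 0.0118 in DESeq2, and without hyperoxia replicate 2 it was 0.98 with an adjusted p of 0.286 in edgeR. Ncf1 differed by -0.08 ± 0.22, Cyba by 0.21 ± 0.28 and the proton channel gene Hvcn1 by -0.31 ± 0.40, with a strand overlap with Tctn1. Cyba stood at -0.12 without hyperoxia replicate 2, and Ncf1 at 0.07 without normoxia replicate 3 and at 0.01 without hyperoxia replicate 2. Antioxidant and NRF2 target genes had a median of 0.17 over 23 members with an adjusted p of 0.242, and of 0.36 without normoxia replicate 1. Catalase (Cat, 1.41 ± 0.34) and the glutathione peroxidase gene Gpx3 (1.95 ± 0.48) passed when adjusted over the list alone and in DESeq2, and Srxn1 (0.70 ± 0.26) did not. Cat and Gpx3 averaged 2.66 and 1.39 CPM in normoxia, and the mean scores of macrophage, endothelial and stromal markers were also higher in hyperoxia.

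Cytokine, interferon and effector genes showed no list-wide difference. NF-kappaB and inflammatory cytokine genes had a median of 0.06 over 31 members (adjusted p of 0.929, on the lower side in camera), with a median of 0.44 and an adjusted p of 0.00769 without hyperoxia replicate 2, and a median of -0.16 and an adjusted p of 0.144 without hyperoxia replicate 3. Ccl2, a chemokine that recruits monocytes, averaged 194 ± 118 against 60.8 ± 6.14 CPM (SD, n = 3 each), Traf1 differed by 1.13 ± 0.34 (SE) and Il6 by 2.50 ± 0.80, with Ccl2 at 1.07 without hyperoxia replicate 2 and Il6 at 1.41 and Traf1 at 0.66 without hyperoxia replicate 3; 0 members passed when adjusted over the list alone, 3 were under an unadjusted p of 0.05 and DESeq2 called 3. Il6 had at most 14 counts in a normoxia library and stood at 0.28, 1.22 and 3.37 CPM in the hyperoxia libraries. Il1b, at 39690 ± 2574 CPM in normoxia and 35600 ± 12340 CPM in hyperoxia (SD, n = 3 each), differed by -0.16 ± 0.31 and, without hyperoxia replicate 2, by 0.12. Tnf differed by -0.02 ± 0.66, with values from -1.33 without hyperoxia replicate 3 to 0.44 without hyperoxia replicate 2. Type I interferon response genes had a median of -0.15 over 29 members (adjusted p of 0.448), and without hyperoxia replicate 1 a median of -0.56 with an adjusted p of 2.62e-04; the median was 0.08 without normoxia replicate 1, 0.08 without hyperoxia replicate 2 and 0.02 without hyperoxia replicate 3. Mx1, an interferon-induced antiviral gene, passed when adjusted over the list alone (1.90 ± 0.40), while Ifi44 (1.14 ± 0.35) and Irf9 (-0.48 ± 0.26) did not.

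Cytotoxic ligands and effectors had a median of 0.22 over 9 members, on the lower side in camera (adjusted p of 0.919), with the TNF family gene Tnfsf14 at -0.59 ± 0.23 (SE), Ifng at 2.32 ± 1.06 and Nos2, the inducible nitric oxide synthase, at 0.96 ± 0.64. Without hyperoxia replicate 1, which held 576 CPM of Nos2, that gene stood at -0.01 and the list's median at -0.01. Without hyperoxia replicate 3 the median was -0.37 and Ifng stood at 0.13, and without hyperoxia replicate 2 the median was 0.44. Ifng had at most 15 counts in a normoxia library. Suppressive and tumour-promoting neutrophil genes had a median of 0.29 over 18 members (adjusted p of 0.193), with a median of 0.43 and an adjusted p of 0.0393 without hyperoxia replicate 2, and of 0.15 and 0.937 without hyperoxia replicate 1. The anti-inflammatory cytokine gene Il10 differed by 1.78 ± 0.47, the prostaglandin synthase gene Ptges by 0.70 ± 0.31, Tgfb1 by -0.39 ± 0.19, Arg1 by 0.62 ± 0.37 and Cd274, which encodes the checkpoint ligand PD-L1, by 0.22 ± 0.46. Il10 was low, at 0.94 to 1.40 CPM in normoxia and 3.39, 2.15 and 7.16 CPM in hyperoxia. DESeq2 called Il10 and no other member of the list, and it did not pass in edgeR when adjusted over the list alone. Its highest value came from hyperoxia replicate 3, which also had the highest macrophage score, and which cells carried Il10 was not tested. Cd274 stood at -0.07 without hyperoxia replicate 1, at 0.66 without hyperoxia replicate 2 and at 0.00 without hyperoxia replicate 3. Angiogenesis genes had a median of 0.77 over 9 members, with an adjusted p of 0.193 in camera and 0.0408 in fry, and a mean 0.50 above normoxia (95% interval 0.11 to 0.88, adjusted p of 0.146 in limma). Mean scores of endothelial, stromal and macrophage markers were also higher in hyperoxia, by 2.77, 1.88 and 1.38. Stromal scores overlapped between groups, with hyperoxia replicate 1 at 0.15 and normoxia replicate 3 at 0.84 relative to the normoxia mean. The angiogenesis genes with the lowest p were Angptl4 (1.76 ± 0.48, called by DESeq2), Thbs1 (1.11 ± 0.52, and 0.38 without hyperoxia replicate 1) and Hbegf (-0.98 ± 0.47).

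The genes that define neutrophils varied more between hyperoxia libraries than between groups. Neutrophil markers had a median of 0.26 over 12 members with an adjusted p of 0.448, with a median of 0.42 and an adjusted p of 0.0196 without hyperoxia replicate 3, and of 0.17 and 0.867 without hyperoxia replicate 1. Ly6g, the sorting marker, stood at 196.3, 351.2 and 38.9 CPM in hyperoxia and differed by 1.11 ± 0.69 (SE). S100a8 stood at 23880, 44970 and 13240 CPM and differed by 0.65 ± 0.43, S100a9 by 0.50 ± 0.38, Retnlg by 1.87 ± 0.86 and Mmp9 by 0.22 ± 0.40. Without hyperoxia replicate 2 these stood at 0.40 (Ly6g), 0.11 (S100a8), 0.15 (S100a9), 0.43 (Retnlg) and -0.25 (Mmp9). Epithelial markers had a median of 0.29 over 13 members but lay on the lower side in camera (adjusted p of 0.236), with scores of 0.75, -2.90 and 0.58 in the hyperoxia libraries; without hyperoxia replicate 2 the median was 0.78 with an adjusted p of 0.0149, without hyperoxia replicate 1 it was -0.13 with an adjusted p of 0.0239, and without hyperoxia replicate 3 it was -0.21 with an adjusted p of 0.0817. Spint2 differed by -0.47 ± 0.28 and Cdh1 by 0.43 ± 0.43, or by 0.05 without hyperoxia replicate 1. Hyperoxia replicate 2 stood apart from the other libraries: it lay at 91.1 on a first principal component that held 42.5% of the variance, where the others lay between -36.8 and 18.9.

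**Figure D3:**
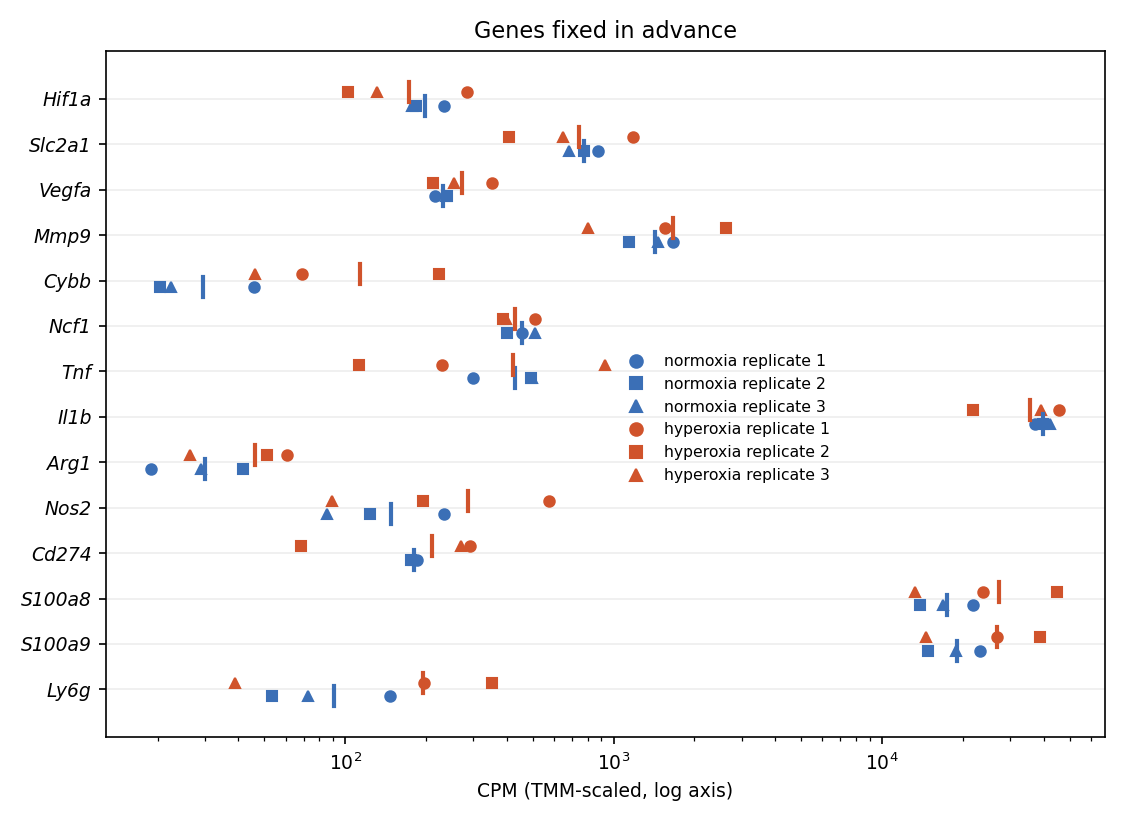
CPM (TMM-scaled, log axis) of genes fixed in advance, with 1 point per library, normoxia in blue, hyperoxia in orange and a vertical bar at each group mean. The groups do not overlap for Cybb, and hyperoxia replicate 2 holds the highest value of Cybb (223.9 CPM), Ly6g (351.2 CPM) and S100a8 (44970 CPM).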

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

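DESeq2 with single hyperoxia libraries left out, edgeR without robust estimation, and camera under upper-quartile scaling, library size alone, no filter or removal of abundant gene classes were tests chosen after the data were seen; the other alternatives were planned. The number of genes past the threshold depended on the tool and the libraries. Against 0 higher and 0 lower in edgeR (1680 at an unadjusted p under 0.05), DESeq2 called 461 higher and 52 lower, voom with sample weights 35 and 1, edgeR without the low-count filter 205 and 9 (198 of them also called by DESeq2), and a threshold of 0.1 gave 28 and 2. Leaving out each library in edgeR gave 0 to 164 higher and 0 to 12 lower genes, the calls coming without hyperoxia replicate 1. DESeq2 called 836 higher and 276 lower without hyperoxia replicate 1, 406 and 63 without replicate 2, and 397 and 170 without replicate 3. All other gene-level settings gave 0 in both directions. The fry test passed 4 lists, of which angiogenesis was not among the 12 past the threshold in camera. Camera's lists went from 12 to 0 with an estimated correlation and ranged from 8 to 15 over the libraries left out. The macrophage, MHC class II, endothelial, stromal and smooth muscle lists passed in all 6 of these. Of 135 named genes, 118 had 1 sign under every setting and 17 did not. All 12 lists past the threshold kept theirs. So did the 20 genes named for a low p at an average log2 CPM of at least 3. Those 20 were chosen with groups that do not overlap, so leaving out a library could hardly turn their sign. The median log2 difference of all genes, 0.04, ranged from -0.02 (limma-voom, and -0.01 with sample weights) to 0.12 (without normoxia replicate 1), with 0.11 without the filter or without normoxia replicate 3. The cause of these shifts was not tested, except that the looser filter adds genes with few counts. No paired analysis was possible because replicate numbers only follow the order of deposition.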

Other observations

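Among unfolded protein and integrated stress response genes (16 members, median 0.03, with -0.20 without hyperoxia replicate 3 and 0.12 without hyperoxia replicate 2, camera adjusted p of 0.421), the chaperone cofactor gene Sdf2l1 had a log2 difference of 0.89 ± 0.25 (SE), while the stress transcription factor genes Ddit3, which overlaps Mars on the opposite strand, and Atf3 stood at -1.04 ± 0.31 and -0.76 ± 0.23; fry's test for change in either direction gave an adjusted p of 0.0322, and 0 members passed in edgeR when adjusted over the list alone, with 6 under an unadjusted p of 0.05 and 1 called by DESeq2. Apoptosis and survival genes had a median of -0.05 over 19 members (adjusted p of 0.11), -0.16 (0.0318) without hyperoxia replicate 1 and 0.07 without hyperoxia replicate 2, with the p53 targets Bbc3 at -0.64 ± 0.23 and Pmaip1 at -0.56 ± 0.26 and the inhibitor gene Xiap at -0.42 ± 0.24. Phagocytosis and innate sensing genes had a median of 0.07 over 20 members (0.929), -0.04 without hyperoxia replicate 1 and 0.22 without hyperoxia replicate 2, with Pycard at 0.59 ± 0.30 and Nlrp3 at 0.67 ± 0.43. Their member Msr1 passed in edgeR when adjusted over the list alone and was called by DESeq2. Adhesion and chemotaxis genes had a median of 0.08 over 18 members (0.929), 0.01 without normoxia replicate 2 and 0.24 without normoxia replicate 1, with Fpr2 at 0.58 ± 0.23 and Ceacam1 at 1.01 ± 0.45, or 0.24 without hyperoxia replicate 2. MHC class I presentation genes had a median of 0.03 over 10 members, all between -0.13 and 0.27 (0.929), Psmb10 at 0.27 ± 0.26, B2m at -0.13 ± 0.22 and H2-D1 at 0.12 ± 0.22. Their median was 0.21 without normoxia replicate 1 and -0.09 without hyperoxia replicate 1, Psmb10 stood at -0.03 without hyperoxia replicate 2 and B2m at 0.02 without normoxia replicate 3.

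Oxidative phosphorylation genes had a median of 0.02 over 46 members (adjusted p of 0.929), 0.24 (0.0492) without hyperoxia replicate 1 and -0.10 (0.0422) without hyperoxia replicate 2, with Ndufa9 at 0.83 ± 0.28, Cox8a at -0.53 ± 0.19 and Ndufa5 at 0.89 ± 0.42. Transcripts of the mitochondrial genome had a median of 0.41 over 7 members (0.13), 0.65 (0.0419) without normoxia replicate 3, 0.62 (0.00856) without hyperoxia replicate 2 and 0.08 (0.483) without hyperoxia replicate 3, with mt-Co1 at 0.75 ± 0.25, mt-Nd5 at 0.49 ± 0.27 and mt-Nd6, which overlaps it on the opposite strand, at 0.42 ± 0.29. Cytosolic ribosomal protein genes had a median of -0.02 over 36 members (0.929), a sign that turned with upper-quartile scaling and without normoxia replicates 2 or 3 or hyperoxia replicates 1 or 2 (0.14 without hyperoxia replicate 1, the highest), with Rpl4 at 0.74 ± 0.24, Rps4x at 0.86 ± 0.40 and Rps18 at 0.54 ± 0.36. Circadian clock genes had a median of 0.18 over 12 members (0.929), 0.47 without hyperoxia replicate 1 and 0.37 without normoxia replicate 1, with Arntl at 1.06 ± 0.42, Per2 at 0.59 ± 0.32 and Ciart at -0.65 ± 0.38. Erythroid markers had a median of 0.37 over 5 members (0.466) and were high in 1 library of each group, Hbb-bs standing at 397 CPM in normoxia replicate 3 and 453.8 CPM in hyperoxia replicate 3, with Alas2 at 0.43 ± 0.96 and Hbb-bt at 0.37 ± 1.02. The erythroid median was 2.43 (0.00454) without normoxia replicate 3, -1.05 without hyperoxia replicate 3, and -0.13 without normoxia replicate 1 or 2, where Alas2, Hbb-bs and Hbb-bt turned sign as well. Of the lists too small for camera, eosinophil markers held Siglecf at -1.16 ± 0.37, Ear2 at 1.93 ± 0.58, both past the threshold when adjusted over the list alone, and Ccr3 at -0.90 ± 0.42, platelet markers held Pf4 at 1.69 ± 0.61, Ppbp at -2.23 ± 1.03 (-0.15 without normoxia replicate 2) and Itga2b at -0.12 ± 0.67 (0.55 without normoxia replicate 2 and 0.21 without hyperoxia replicate 1), and mast cell markers held Kit at 1.08 ± 0.80, or -0.63 without hyperoxia replicate 2.

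Of the tests reported next, the comparison of macrophage markers with those of other cell types, whose choice of lists was revised after their values were seen, the test of depth between groups and the count of splits for adjusted edgeR calls were chosen after the result was seen. The lists of further macrophage genes and of blood, marrow and activated neutrophil genes were written after the leading genes and list scores were known, and before their own values were. Monocyte and macrophage markers were higher in all 3 hyperoxia libraries, and deeper sequencing is argued against, since without hyperoxia replicate 2, the deepest library, the markers' median log2 difference was 1.54. A candidate explanation is that more monocytes or macrophages, which the Ly6G-high gate should remove, entered the sort. For it, 25 further macrophage genes outside the fixed lists had a median of 1.26 (quartiles 0.47 and 2.17). That lay above all of 10000 random lists matched on expression. Random genes do not vary together as macrophage genes do, so this rank decides little (estimated correlation of the fixed macrophage markers 0.294). In hyperoxia replicate 1, Folr2 (0.71 CPM, normoxia up to 0.95) and Gas6 (0.81 CPM, normoxia up to 1.46) lay within the normoxia range. Pltp (5.04 CPM, normoxia up to 3.31) and Dab2 (13.06 CPM, normoxia up to 7.1) lay above it. A lower share of neutrophils with every other cell type raised alike cannot be told apart from macrophages entering the sort. Of 8 other marker lists with at least 5 measured members, endothelial markers lay furthest apart by p. Macrophage minus endothelial scores differed by -1.39 (interval -2.79 to 0.01, adjusted p of 0.409 in limma). The epithelial comparison was wide (1.90, interval -0.99 to 4.79). The 4 measured eosinophil markers did differ (1.49, interval 1.02 to 1.96), but they were too few to count in that comparison. Their members went both ways, from Siglecf at -1.16 to Ear2 at 1.93, so the score is no clear measure of an eosinophil share. Epx and Ear1, also on that list, had 0 counts. Csf1r stood at 181 CPM in both groups, and how far added macrophages would raise it was not estimated. Expression of macrophage genes by the neutrophils of hyperoxic mice was not tested and would raise these lists as well.

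Hyperoxia replicate 2 lay apart from the other libraries. Its depth is argued against: after every library was thinned to the size of the smallest, its mean Pearson r across genes with the other 5 libraries was 0.931, and 0.932 before, while the lowest such value among the others was 0.955. A candidate explanation is a larger part of neutrophils with a blood or marrow profile. For it, 16 genes of that profile scored 1.42 above the highest other library, the others spanning a range of 0.78. Another 14 genes of tissue activation scored 0.46 lower than the lowest other library, less than the others' range of 0.57. Relative to the normoxia mean, this library also scored -2.90 for epithelial, 3.59 for endothelial, 2.33 for smooth muscle and 2.52 for B cell markers. A neutrophil profile would not cover those differences. Stored granule genes were high in this library as well, with Ngp at 5548 CPM and at most 515 CPM in the others. Granule scores were known before the blood and marrow list was written, so they add no separate support. Whether housing, dissection or the individual sample set this library apart was not tested.

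The 6 libraries make only 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 1680 genes at an unadjusted p under 0.05 in edgeR and the highest other split 1407, so 1 of 10 was as large; in DESeq2 these were 513 and 347, again 1 of 10. For the macrophage markers' median they were 1.58 and 1.13, also 1 of 10. At an adjusted p of 0.05 in edgeR all 10 splits gave 0 genes. For gene lists in camera, 4 of the 10 splits, the real split among them, passed at least 12, and the highest passed 20 by setting normoxia replicate 2 with hyperoxia replicates 2 and 3 against the rest.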
